A study of Mus musculus with 6 samples.

How the data were processed

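RNA from mouse hepatic stellate cells was measured on 6 Affymetrix arrays, 1 for each of 2 ages and 3 states, with cells of 5 mice pooled in each sample, per the labels. Per the labels' protocols, RNA was purified with RNeasy columns and labelled with the GeneChip WT PLUS kit. The deposited values are log2 signals, and per the submitters' processing notes they were made with Affymetrix Expression Console and RMA. Versions and options are not given in the sources used here. RMA stands for background correction, quantile normalization and a summary for each probe set, and the deposited arrays still differed in their medians and spread, so their quantiles were not aligned at the level of probe sets.

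All further values were computed from the deposited log2 values. The platform's table gave 1 gene symbol for 23521 of 41345 probe sets, several for 1814 and no gene for 16010, and the last 2 kinds entered no test. A gene with several probe sets was represented by the probe set with the highest mean signal, which gave 22180 genes. The RefSeq table of GRCm38.p6 served for names only. The 30% of genes with the lowest mean over the 6 arrays (a mean log2 signal under 4.70) were left out, which left 15526. No array was left out of the main tests.

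Differences were tested with limma 3.58.1 in R 4.3.3 on a model with age and state, with moderated variances and an intensity trend (2 residual degrees of freedom, prior degrees of freedom 7.76). P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. The comparisons were vehicle minus quiescent (called activation), PRI-724 minus vehicle, PRI-724 minus quiescent, and old minus young over the 3 states. The standard error (SE) is that of limma's moderated fit. With 1 array in each group, the error of the state comparisons is the disagreement between ages over all 3 states. In the age comparison the same deviation is the disagreement between states. All comparisons share it. A count of genes at least 2-fold apart in the same direction in every pair was made without a test. The age difference of a response was described without a test.

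Lists of 38 pathways and cell types with 600 genes were written in advance, and 513 of these genes were tested. Lists with at least 3 tested genes were tested with camera from limma at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Every list was also tested with the correlation estimated from the data, and the genes of a list were in addition adjusted over the list alone. Genes named in the text were the 10 with the largest rise and the 10 with the largest fall among those past the threshold with the same sign in every pair (5 and 5 for PRI-724 minus quiescent), 20 genes always named, and up to 4 members of each list with the largest mean absolute difference. Predicted and unnamed genes, small RNAs, histone genes, receptor segments and olfactory and vomeronasal genes were skipped. These choices, the comparisons and the alternatives below were made before the data were examined.

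The alternatives were no filter on signal, a filter of the lowest 50%, the mean of all probe sets of a gene, no intensity trend, no age (or state) in the model, only the arrays of the states compared, cyclic loess of the tested genes, a 1.5-fold limit, and each array left out in turn. Quantile normalization of the tested genes and the rotation test fry in place of camera were chosen after seeing the data. The model was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold for each comparison over 15526 genes, with 1 to 5 false calls and 0 calls of the wrong sign. Noise was drawn independently for each gene, and the number of changed genes was not matched to the numbers called in the data. The recovered shares describe that setting and not the sensitivity of the real tests. Median positions of lists among random lists used 10000 draws matched on mean signal in 20 bins. The expected correlation of 2 comparisons that share an array came from 20 simulations of unchanged groups. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.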

Results

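Transcript levels were measured on 6 Affymetrix arrays in mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver that turn into contractile, collagen-producing myofibroblasts in culture or in injured liver. The cells came from young mice (8 to 11 weeks) or old mice (6 to 9 months), and each sample was a pool from 5 mice. For each age there were 3 states. Quiescent cells had been plated for 12 h. Activated cells had been kept in culture for more than 20 days and were given vehicle, or C-82 at 10 µM. C-82 is the active form of PRI-724, an inhibitor of the binding of beta-catenin to the coactivator CBP, and the treated samples are called PRI-724 below. The labels do not give the time of exposure to C-82. Each of the 6 groups had 1 array, so no group has a spread of its own. The limma p-values set a difference between states (n = 2 pairs) against the disagreement between ages over all 3 states. That spread is moderated by the spread of the other genes. It is thus not the disagreement of the 2 compared pairs alone. The number of arrays limits the precision.

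Probe sets naming a single gene gave 15526 genes with enough signal to be tested. The young PRI-724 array stood apart from the other 5. The interquartile range of its tested genes was 1.71 log2 units, against 2.11 on the old quiescent array and 2.43 on the young vehicle array, the lowest and highest of the others. Across all probe sets, and not only those of tested genes, its correlation with the young vehicle array was 0.916. Its highest correlation was with the old PRI-724 array at 0.953, next to 0.951 with the old quiescent array. On the same probe sets the old PRI-724 array correlated at 0.971 with the old vehicle array. In the young pair, the brightest 25% of genes had a median PRI-724 minus vehicle difference of -0.42 and the dimmest 25% a median of 0.37. The same medians in the old pair were 0.00 and 0.00 to 2 decimals. The first 3 principal components of the 6 arrays held 41.2%, 32.1% and 15.0% of the variance.

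The first comparison asked what culture activation did to quiescent cells. Many genes of the myofibroblast programme rose. Col12a1, a fibril-associated collagen, rose by 4.38 ± 0.49 log2 units (SE, n = 2 pairs), Lox, which crosslinks collagen, by 4.02 ± 0.69, and Acta2, the smooth muscle actin that marks activated stellate cells, by 3.66 ± 0.41 or 12.6-fold. The other genes with the largest rises were Ogn, an extracellular matrix proteoglycan, at 4.12 ± 0.51, Apln, the ligand of the apelin receptor, at 3.84 ± 0.60, Nid2 of the basement membrane at 3.55 ± 0.38, S100a6 at 3.53 ± 0.39, the tubulin gene Tuba1a at 3.42 ± 0.38 and the protease gene Mmp10 at 3.39 ± 0.31. Col1a1 rose by 2.91 ± 0.48, Timp1, an inhibitor of matrix proteases, by 2.58 ± 0.39, and Mmp2, a gelatinase, by 1.86 ± 0.29. Of the 20 genes of the protease and inhibitor list 5 rose and 0 fell, 6 and 1 adjusted over the list alone, with a median of 0.17, and the list was not called (adjusted p = 0.0887). In total 716 genes rose and 195 fell of 15526 (limma, adjusted p of 0.05), and 3484 had an unadjusted p under 0.05. At least 2-fold in both pairs, 630 genes were higher, 179 were lower and 17 went in opposite directions.

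Of the 28 tested genes of the fibrillar collagen and matrix list, 14 rose and 0 fell over all genes tested, and 22 rose when adjusted over the list alone. The list had a median difference of 1.17 (camera, adjusted p = 1.44e-12, adjusted p = 0.593 with an estimated correlation). Col5a2 rose by 3.13 ± 0.37, and Col1a2 stood at 1.14 ± 0.38 with an adjusted p of 0.113. Of 17 contractile genes 7 rose, 12 adjusted over the list alone, with a median of 0.98 (adjusted p = 1.8e-07, adjusted p = 0.644 with an estimated correlation). Myl9, a myosin light chain, rose by 3.07 ± 0.36 and Cnn2, a calponin, by 1.86 ± 0.31. Among 13 targets of YAP and TAZ, coactivators that respond to cell stretch, 5 rose, 8 adjusted over the list alone (adjusted p = 1.5e-06, adjusted p = 0.593 with an estimated correlation). These included Nt5e at 3.51 ± 0.51, Ajuba at 1.99 ± 0.40 and Amotl2 at 1.38 ± 0.28.

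Growth-related lists were also called higher. Of 26 cell cycle genes 5 rose, 11 adjusted over the list alone (adjusted p = 6.38e-06, adjusted p = 0.644 with an estimated correlation), among them Rrm2, a subunit of ribonucleotide reductase, by 1.71 ± 0.32 and Ccna2, cyclin A, by 1.28 ± 0.27. Mki67 stood at 0.67 ± 0.30 with an adjusted p of 0.219. Of 17 growth factor genes 6 rose, 7 adjusted over the list alone (adjusted p = 0.0178, adjusted p = 0.593 with an estimated correlation), including the PDGF receptors Pdgfrb by 1.73 ± 0.26 and Pdgfra by 1.90 ± 0.40. Of 20 genes of TGF-beta signalling 4 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.0142, adjusted p = 0.688 with an estimated correlation). Tgfb3, a ligand, rose by 2.07 ± 0.34, Tgfbi, a secreted matrix protein, fell by 1.95 ± 0.37, and Tgfb1 stood at 0.25 ± 0.27. Of 17 cholesterol synthesis genes 4 rose, 10 adjusted over the list alone (adjusted p = 3.97e-05, adjusted p = 0.686 with an estimated correlation), and of 16 genes of hypoxia and glycolysis 3 rose, 8 adjusted over the list alone (adjusted p = 0.002, adjusted p = 0.686 with an estimated correlation). Examples are Lss, an enzyme of sterol synthesis, at 1.78 ± 0.33 and Ldha, lactate dehydrogenase A, at 1.25 ± 0.30. Without the young vehicle array the hypoxia list had an adjusted p of 0.163. The TGF-beta list lost its call without the old quiescent array (adjusted p = 0.0738) or the young vehicle array (0.0675), and the growth factor list lost it without the young (0.102) or old (0.103) PRI-724 array. Both also lost it after cyclic loess (0.0560 and 0.0726) and with the lowest 50% of genes left out (0.0728 and 0.0650).

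Several inflammatory genes were lower in activated cells. Of 25 chemokine and inflammation genes 11 fell and 0 rose, 15 and 2 adjusted over the list alone, with a median of -1.59 (adjusted p = 3.38e-11, adjusted p = 0.571 with an estimated correlation). The neutrophil-attracting chemokines Cxcl2 and Cxcl1 fell, at -4.07 ± 0.47 and -3.52 ± 0.43, as did Ccl5, a T cell attractant, at -3.63 ± 0.48. Cxcl3 and Cxcl9 stood at -3.89 ± 0.56 and -3.44 ± 0.68, Acod1, the itaconate-producing enzyme of macrophages, at -3.48 ± 0.38, and Saa2, an acute-phase protein, at -3.14 ± 0.67, and all 4 passed the threshold. The inducible heat shock genes Hspa1b and Hspa1a fell, at -3.55 ± 0.37 and -3.20 ± 0.44. They belong to the 20 immediate early and dissociation genes, of which 4 fell, 7 adjusted over the list alone (adjusted p = 8.14e-06, adjusted p = 0.593 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response 5 fell, 8 adjusted over the list alone (adjusted p = 2.2e-05, adjusted p = 0.593 with an estimated correlation), such as Mthfd2, a mitochondrial folate enzyme, by 1.44 ± 0.29. Among 22 interferon-stimulated genes 2 fell, 4 adjusted over the list alone (adjusted p = 1.5e-06, adjusted p = 0.686 with an estimated correlation), namely Rsad2 by 2.26 ± 0.44 and Oasl1 by 2.10 ± 0.50. Among 11 genes of MHC class I presentation 2 fell, 2 also adjusted over the list alone (adjusted p = 0.00104, adjusted p = 0.686 with an estimated correlation), H2-Q4 by 1.80 ± 0.28 and H2-K1 by 0.88 ± 0.22. Without the young quiescent array the interferon list had an adjusted p of 0.0705 and the MHC list one of 0.305.

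The quiescent stellate cell list was not called. Of 14 tested genes 6 rose and 1 fell, 7 and 2 adjusted over the list alone, with medians of 0.44 in the young and 0.83 in the old pair (adjusted p = 0.102). Lrat, which makes retinyl esters, rose by 1.34 ± 0.31, Des, desmin, by 2.39 ± 0.38 and Hand2, a mesenchymal transcription factor, by 2.20 ± 0.31, while Reln stood at 0.50 ± 0.27 and Gfap at -0.04 ± 0.27. Of 19 Wnt/beta-catenin targets 0 rose and 1 fell, 1 and 1 adjusted over the list alone (adjusted p = 0.911). The list had a median of 0.07, while its test pointed downward. The gene that fell was Myc, by 1.13 ± 0.24. Axin2 stood at -0.36 ± 0.29 and Ccnd1, cyclin D1, at 1.54 ± 0.60 with an adjusted p of 0.169.

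Some lists of other liver cells were called with activation too. Of 17 hepatocyte genes 3 fell, 14 adjusted over the list alone, with a median of -1.50 (adjusted p = 1.15e-10, adjusted p = 0.644 with an estimated correlation). The median was -0.79 in the young pair and -1.88 in the old pair, and the fallen genes include Serpina1c at -3.20 ± 0.38 and Ahsg at -2.57 ± 0.47, both encoding plasma proteins. Of 7 mesothelial genes 2 rose, 5 adjusted over the list alone (adjusted p = 0.000855, adjusted p = 0.593 with an estimated correlation), the larger change being Upk1b at 2.48 ± 0.28. Macrophage markers had a median of -0.09 and sinusoidal endothelial markers one of 0.03, and neither list was called (adjusted p = 0.224 and 0.615). The number of genes past the threshold fell from 911 to 318 without the young vehicle array, to 484 without the young PRI-724 array and to 489 without the old PRI-724 array, and was 482 after cyclic loess and 114 without age in the model. In simulated data for this comparison, with independent genes and fewer changed genes than were called here, 89% of 4-fold and 3% of 2-fold changes were recovered.

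**Figure D1:**
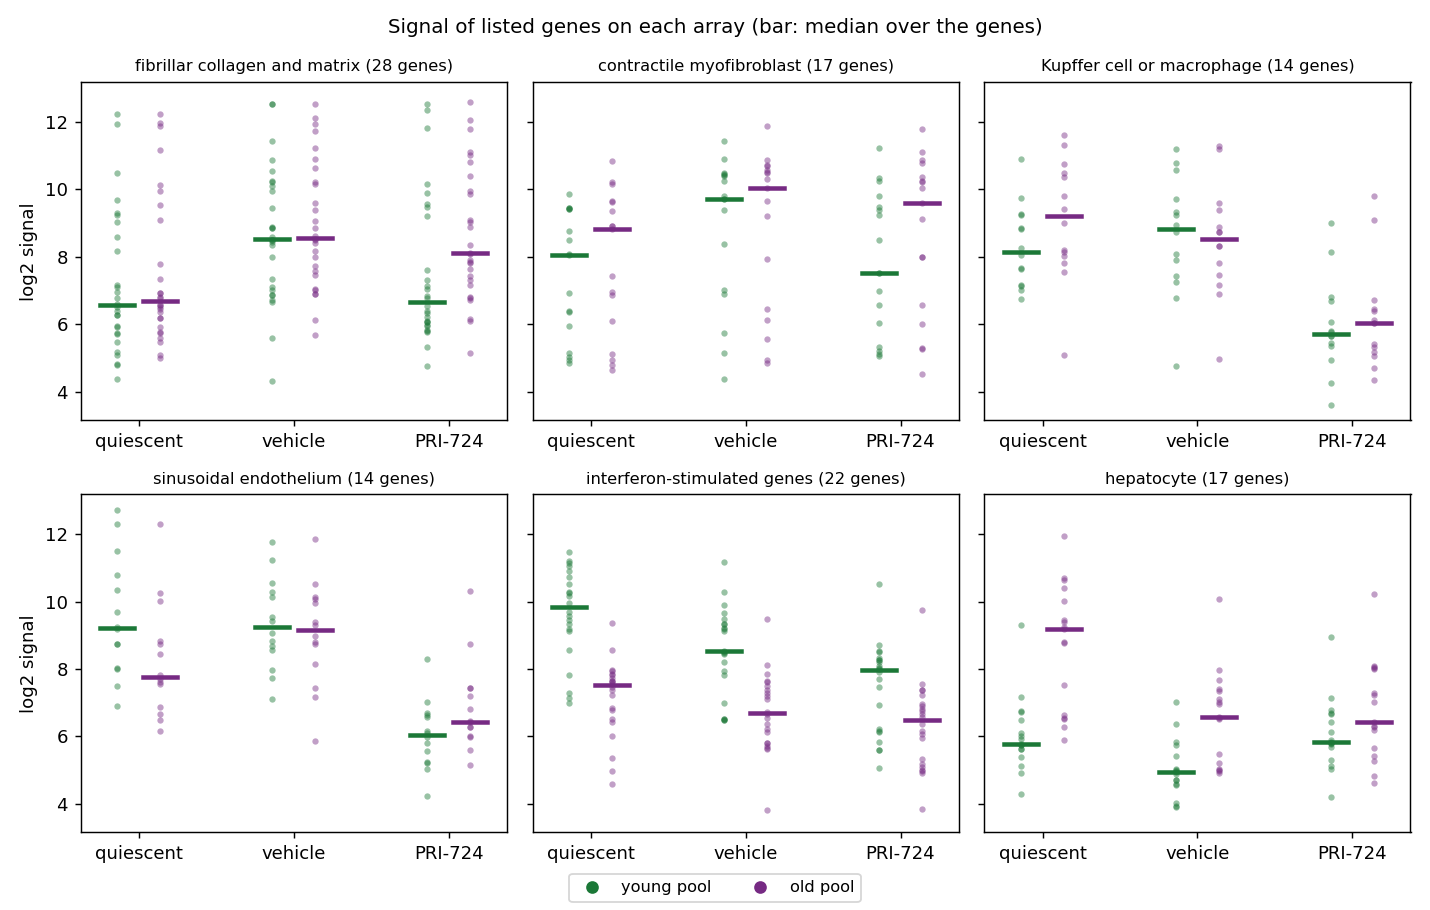
Log2 signal (y axis) of the tested genes of 6 lists on each of the 6 arrays, with the 3 states on the x axis, young pools in green and old pools in purple, a point for each gene and a bar for the median over the genes. The macrophage list has a median of 8.84 and 8.53 on the young and old vehicle arrays and of 5.71 and 6.04 on the PRI-724 arrays.

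The second comparison asked what PRI-724 did to activated cells. The genes that fell furthest are known from macrophages and from liver sinusoidal endothelium, the fenestrated lining of the liver capillaries. Vsig4, a complement receptor of Kupffer cells, fell by 5.08 ± 0.33 log2 units (SE, n = 2 pairs), as did Cd5l, a secreted macrophage protein, at -5.14 ± 0.51, and Ccl6, a chemokine, at -5.33 ± 0.94. Oit3 and Fcgr2b, markers of sinusoidal endothelium, fell, at -4.76 ± 0.35 and -3.80 ± 0.43. Cybb, the NADPH oxidase subunit of phagocytes, fell by 3.88 ± 0.29, and the C-type lectin genes Clec7a, Clec12a and Clec1b fell too, at -4.09 ± 0.50, -3.89 ± 0.38 and -3.85 ± 0.35. Igsf6 fell by 4.22 ± 0.39. In total 299 genes fell and 42 rose (limma, adjusted p of 0.05), and 2404 had an unadjusted p under 0.05. At least 2-fold in both pairs, 366 genes were lower, 57 were higher and 3 went in opposite directions.

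Of 14 macrophage markers 10 fell, 13 adjusted over the list alone, with a median of -2.65 in the young pair and -2.28 in the old pair (adjusted p = 1.75e-17, adjusted p = 0.643 with an estimated correlation). Examples are Mpeg1 at -3.41 ± 0.31 and Marco, a scavenger receptor, at -3.14 ± 0.65. Of 14 sinusoidal endothelial markers 13 fell, 14 adjusted over the list alone, with medians of -3.15 and -1.91 (adjusted p = 1.19e-17, adjusted p = 0.643 with an estimated correlation). The hyaluronan receptors Stab1 and Stab2 fell, at -3.56 ± 0.42 and -3.45 ± 0.59. Both lists kept their calls without the young PRI-724 array and after cyclic loess.

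The lists of retinoid and lipid droplet genes and of matrix proteases were called lower as well. Of 23 retinoid and lipid genes 7 fell, 8 adjusted over the list alone, with a median of -0.50 (adjusted p = 4.85e-05, adjusted p = 0.643 with an estimated correlation). They include the fatty acid carriers Cd36 at -3.74 ± 0.41 and Fabp4 at -3.10 ± 0.55, which endothelial cells and macrophages also express, the retinaldehyde dehydrogenase Aldh1a1 at -2.13 ± 0.45 and Lrat at -1.69 ± 0.31. Of 20 protease and inhibitor genes 4 fell, 6 adjusted over the list alone (adjusted p = 0.0049, adjusted p = 0.643 with an estimated correlation). These were Mmp12, the macrophage elastase, at -3.50 ± 0.46, Plau, the urokinase, at -2.08 ± 0.33, Mmp19 at -1.96 ± 0.28 and Adamts5, an aggrecanase, at -1.85 ± 0.38. Timp1 stood at -0.26 ± 0.39 and Mmp13 at 0.45 ± 0.39. Without the old PRI-724 array the protease list had an adjusted p of 0.073.

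For the genes of the myofibroblast programme the young and the old pair differed in size. Of 28 matrix genes 1 fell, 7 adjusted over the list alone, with a median of -1.07 in the young pair and -0.20 in the old pair (adjusted p = 3.12e-05, adjusted p = 0.643 with an estimated correlation). The gene past the threshold was Col12a1 at -2.46 ± 0.49. Col1a1 stood at -2.78 in the young and -1.05 in the old pair (adjusted p = 0.0803), and Acta2 at -2.73 and -0.90 (adjusted p = 0.0573). Of 17 contractile genes 1 fell, 4 adjusted over the list alone, with medians of -0.90 and -0.09 (adjusted p = 0.0102, adjusted p = 0.717 with an estimated correlation), and that gene was Myl9 at -2.41 ± 0.36. Without the young PRI-724 array the contractile list had an adjusted p of 0.263, and without the young vehicle array one of 0.186. The larger fall lay in the young pair, which holds the PRI-724 array with the narrower signal range. In the old pair the macrophage and endothelial lists still fell, with medians of -2.28 and -1.91, beside -0.20 for matrix and -0.09 for contractile genes. Whether these falls are linked was not tested.

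Other lists called lower held few or no genes past the threshold. Of 26 cell cycle genes 0 fell, 0 also adjusted over the list alone, with a median of -0.57 (adjusted p = 2.69e-05, adjusted p = 0.643 with an estimated correlation), and Mki67 stood at -0.75 ± 0.30. Of 16 genes of hypoxia and glycolysis 0 fell, 9 adjusted over the list alone, with medians of -1.54 and -0.20 (adjusted p = 5.65e-05, adjusted p = 0.643 with an estimated correlation). Of 22 interferon-stimulated genes 0 fell, 1 adjusted over the list alone (adjusted p = 4.85e-05, adjusted p = 0.643 with an estimated correlation, adjusted p = 0.0576 without the young PRI-724 array). Of 17 cholesterol synthesis genes 1 fell, 4 adjusted over the list alone (adjusted p = 0.000303, adjusted p = 0.643 with an estimated correlation, adjusted p = 0.0647 without the young vehicle array), namely Fdft1, squalene synthase, at -1.38 ± 0.29. Of 17 growth factor genes 2 fell, 3 adjusted over the list alone (adjusted p = 0.00566, adjusted p = 0.643 with an estimated correlation, adjusted p = 0.202 without the old PRI-724 array), the PDGF ligands Pdgfd at -2.27 ± 0.36 and Pdgfb at -1.61 ± 0.30. The lists of YAP/TAZ targets, quiescent stellate cells, TGF-beta signalling and apoptosis regulators had adjusted p of 0.0259, 0.0444, 0.0446 and 0.0446. With an estimated correlation these were adjusted p = 0.643, 0.643, 0.720 and 0.643, after cyclic loess adjusted p = 0.0912, 0.109, 0.238 and 0.102, and with the lowest 50% of genes left out 0.126, 0.169, 0.202 and 0.183. In these lists 0 of 13, 2 of 14, 0 of 20 and 0 of 16 genes fell, and 1, 3, 5 and 2 adjusted over the list alone. Without the young PRI-724 array adjusted p was 0.0822, 0.193, 0.372 and 0.0822, and without the young vehicle array 0.426, 0.0527, 0.294 and 0.0527. The first 2 and the apoptosis list also lost their calls without the old PRI-724 array (0.0705, 0.0742 and 0.0890), the TGF-beta and apoptosis lists without the young (0.0922 and 0.0829) or old (0.0882 and 0.0838) quiescent array, and the apoptosis list without the old vehicle array (0.129) or with the mean of all probe sets of a gene (0.0860). The quiescent stellate genes that fell were Lrat and Tcf21, a mesenchymal transcription factor, at -1.84 ± 0.33.

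The list of the unfolded protein and integrated stress response was called higher after PRI-724. Of its 25 genes 3 rose, 8 adjusted over the list alone, with medians of 0.49 in the young and 0.73 in the old pair (adjusted p = 1.76e-05, adjusted p = 0.643 with an estimated correlation, adjusted p = 0.073 without the old PRI-724 array). Trib3, a pseudokinase induced by ATF4, rose by 1.63 ± 0.29 and Slc7a5, a transporter of large neutral amino acids, by 1.63 ± 0.26. Cth, which makes cysteine from cystathionine, rose by 2.37 ± 0.45, and Avil, an actin-binding protein, by 1.87 ± 0.31. Asns and Slc7a11 stood at 1.30 ± 0.39 and 1.95 ± 0.66 (adjusted p = 0.136 and 0.195). The other genes with the largest rises were Srsx, Astx5, Srsy, Pla2g10os, Speer4b and Obox3, between 2.41 ± 0.41 and 1.65 ± 0.33. Srsx, Srsy, Astx5, Speer4b and Obox3 belong to families of near-identical copies, and their values are uncertain where copies share probes. Hepatocyte markers had a median of 0.91 in the young and 0.05 in the old pair, with 0 of 17 past the threshold and 0 adjusted over the list alone (adjusted p = 0.000156, adjusted p = 0.652 with an estimated correlation). Without the young PRI-724 array that list pointed downward (adjusted p = 0.778).

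The compound acts on beta-catenin and CBP, so their targets and partners were named in advance. Of 19 Wnt/beta-catenin targets 0 rose and 0 fell, 1 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.0915). Axin2 stood at 0.55 ± 0.29 (adjusted p = 0.402), Myc at 0.90 ± 0.24 (0.0953), Ccnd1 at -1.48 ± 0.60 (0.279) and Fzd7 at -1.29 ± 0.30 (0.0665). Ctnnb1, the beta-catenin gene, stood at -0.05 ± 0.23, Crebbp, which encodes CBP, at 0.24 ± 0.24, and Ep300 at 0.12 ± 0.27. Lef1 and Birc5 were too dim to be tested. Of 31 genes of Wnt pathway components 0 rose and 0 fell, 0 and 5 adjusted over the list alone (adjusted p = 0.131).

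With limma the count of 341 genes depended on single arrays. Without the young PRI-724 array 0 genes passed and 997 had an unadjusted p under 0.05. The count was 246 without the old PRI-724 array, 744 without the old vehicle array, 968 and 955 without the young and the old quiescent array, and 103 after cyclic loess, 3 higher and 100 lower. In simulated data for this comparison, with independent genes and fewer changed genes than were called here, 90% of 4-fold and 12% of 2-fold changes were recovered.

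**Figure D2:**
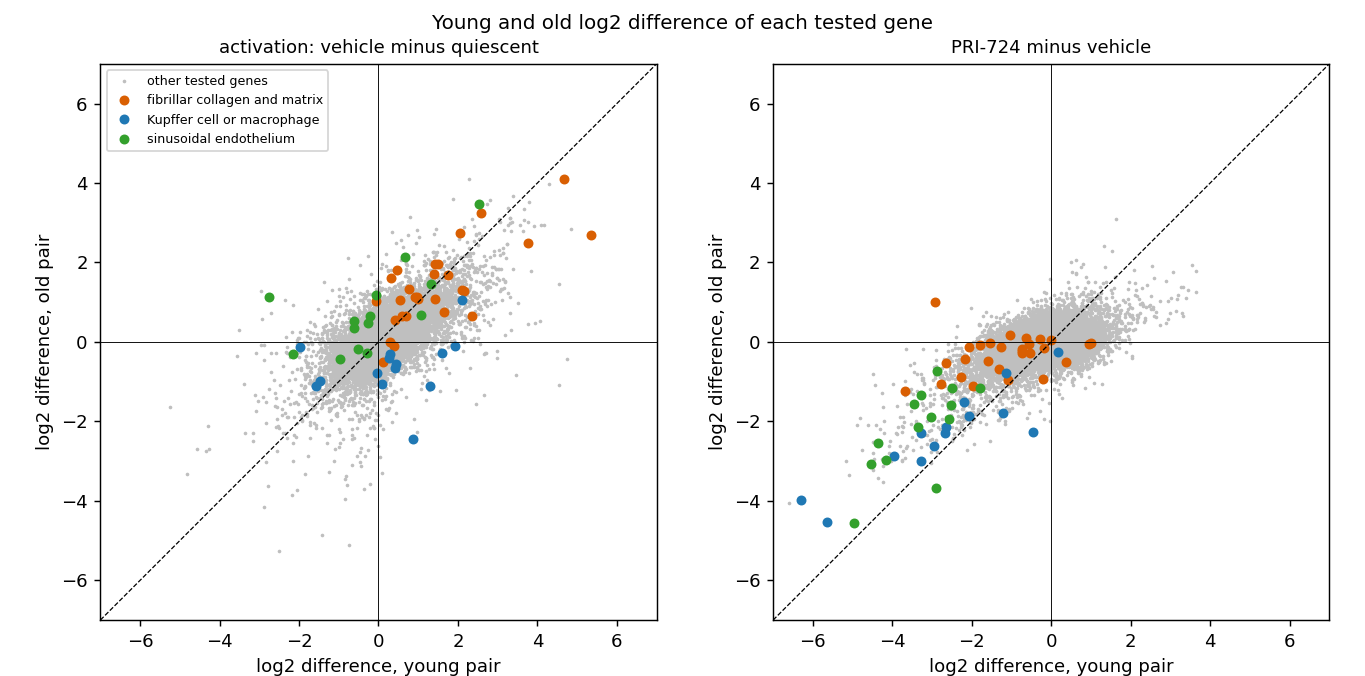
Log2 difference of each of the 15526 tested genes in the young pair (x axis) and the old pair (y axis), for activation on the left and PRI-724 minus vehicle on the right, with 3 lists in colour and the line of equal differences dashed. Across genes Pearson's r is 0.668 for activation and 0.571 for PRI-724, and on the right the matrix list has a median of -1.07 in the young and -0.20 in the old pair.

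The third comparison set PRI-724-treated cells against quiescent cells. Some matrix and contractile genes were higher than in quiescence, among them Lox and Acta2, and most macrophage and endothelial markers were lower. Sema3c, a secreted semaphorin, was higher by 3.51 ± 0.40, Cyp1b1, a cytochrome P450, by 3.49 ± 0.38, Ahnak2 by 3.39 ± 0.30, Chchd10 by 3.15 ± 0.46 and Lgals1, galectin 1, by 3.14 ± 0.25. Acta2 was higher by 1.84 ± 0.41 and Timp1 by 2.33 ± 0.39, whereas Col1a1 stood at 0.99 ± 0.48 (-0.20 in the young and 2.18 in the old pair) and Lrat at -0.35 ± 0.31. Lower were Clec1b at -5.14 ± 0.35, Cd5l at -5.05 ± 0.51, the chemokines Ccl3 at -4.45 ± 0.38 and Ccl9 at -4.34 ± 0.58, and F8, coagulation factor VIII made by endothelium, at -4.19 ± 0.50. Past the threshold (limma) 199 genes were higher and 378 lower, with 2528 at an unadjusted p under 0.05. At least 2-fold in both pairs, 220 genes were higher, 344 lower and 16 opposite.

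Of 28 matrix genes 4 rose, 8 adjusted over the list alone, with medians of 0.25 in the young and 1.05 in the old pair (adjusted p = 9.72e-07, adjusted p = 0.548 with an estimated correlation). Of 17 contractile genes 4 rose, 6 adjusted over the list alone, with medians of 0.27 and 0.88 (adjusted p = 0.000133, adjusted p = 0.737 with an estimated correlation). Without the old PRI-724 array these lists had an adjusted p of 0.054 and 0.180. Of 14 macrophage markers 12 fell, 14 adjusted over the list alone, and of 14 endothelial markers 10 fell, 13 adjusted over the list alone (adjusted p = 2.32e-22 and 6.23e-17, each with adjusted p = 0.548 with an estimated correlation). Of 25 chemokine and inflammation genes 13 fell and 0 rose, 18 and 2 adjusted over the list alone (adjusted p = 6.43e-15, adjusted p = 0.437 with an estimated correlation). Of 22 interferon-stimulated genes 10 fell, 17 adjusted over the list alone, with medians of -1.73 and -0.80 (adjusted p = 2.46e-16, adjusted p = 0.548 with an estimated correlation), such as Rsad2 at -3.50 ± 0.44 and Oas2 at -2.41 ± 0.43. Of 11 MHC class I genes 3 fell, 7 adjusted over the list alone (adjusted p = 5.51e-07, adjusted p = 0.548 with an estimated correlation).

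Immediate early, senescence, retinoid and apoptosis lists were lower too. Of 20 immediate early and dissociation genes 6 fell and 0 rose, 9 and 1 adjusted over the list alone (adjusted p = 3.17e-05, adjusted p = 0.548 with an estimated correlation). Of 13 senescence and secretory genes 2 fell, 5 adjusted over the list alone (adjusted p = 0.00122, adjusted p = 0.548 with an estimated correlation, 0.130 without the old PRI-724 array). Of 23 retinoid and lipid genes 3 fell, 3 also adjusted over the list alone (adjusted p = 0.00604, adjusted p = 0.548 with an estimated correlation, 0.0677 without the young PRI-724 array). Of 16 apoptosis regulators 0 fell, 1 adjusted over the list alone (adjusted p = 0.0257, adjusted p = 0.548 with an estimated correlation, 0.204 without the young PRI-724 array, 0.268 without the young quiescent array, 0.0513 after cyclic loess and 0.0514 with the lowest 50% of genes left out). Of 17 hepatocyte genes 1 fell, 1 also adjusted over the list alone, with medians of 0.15 in the young and -2.16 in the old pair (adjusted p = 1.52e-05, adjusted p = 0.737 with an estimated correlation, 0.522 without the old quiescent and 0.802 without the old PRI-724 array). Of 7 mesothelial genes 1 rose, 3 adjusted over the list alone (adjusted p = 0.000133, adjusted p = 0.548 with an estimated correlation). Of 13 YAP/TAZ targets 1 rose, 4 adjusted over the list alone (adjusted p = 0.000309, adjusted p = 0.548 with an estimated correlation, 0.130 without the old PRI-724 array).

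With limma the count of 577 genes became 0 without the young PRI-724 array, where 2763 had an unadjusted p under 0.05, and 94 without the old one. It was 1053 and 1039 without the young and the old vehicle array, and 217 without age in the model.

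The shift with PRI-724 was compared with that of activation in the other age, where no array is shared. Genes at least 2-fold higher with activation in the old pair (946 genes) had a median PRI-724 minus vehicle difference of -1.01 in the young pair, and 92.9% of them were lower, against 57.8% of all genes. Genes at least 2-fold higher with activation in the young pair (1587 genes) had a median of -0.14 in the old pair, and 63.4% were lower, against 51.4% of all genes. For genes lower with activation the medians were 0.68 in the young pair (430 genes, 74.0% higher against 42.2% of all genes) and 0.06 in the old pair (581 genes, 53.4% against 48.6%). Across genes, which are not independent replicates, activation in old cells and PRI-724 in young cells correlated at -0.481, and activation in young cells and PRI-724 in old cells at -0.145. The covariances were -0.239 and -0.0484, and unchanged groups with no shared array would give 0. Within an age, where the vehicle array is shared, the correlations were -0.517 in young and -0.337 in old cells, and unchanged groups gave -0.498 in simulation. Those covariances were -0.311 and -0.0932, against -0.0844 in the simulation. Its noise was the moderated residual of the model, which is disagreement between ages and not between replicate arrays. The part of the covariance that comes from the shared array is thus not known.

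Of the 716 genes higher with activation, 67 were among the 299 lower with PRI-724, where independent lists would share 13.8. Of the 195 lower with activation, 27 were among the 42 higher with PRI-724, against 0.528. In the same direction, 7 genes were lower in both comparisons, against 3.76, and 0 were higher in both, against 1.94. The vehicle arrays enter both comparisons, which by construction raises the overlap in opposite directions and lowers that in the same direction.

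The fourth comparison set old against young cells in the same state. Interferon-stimulated genes were lower in the old samples in each of the 3 states. Ifit1, an interferon-induced RNA-binding protein, fell by 3.41 ± 0.39 (SE, n = 3 pairs), with values of -4.54 in quiescent, -3.56 in vehicle and -2.14 in PRI-724 cells. Irf7, the master regulator of type I interferon, fell by 2.48 ± 0.25, Mx2 by 2.84 ± 0.48, Rsad2 by 2.64 ± 0.36 and Oasl2 by 2.44 ± 0.29. The DNA sensors and interferon-inducible genes Zbp1, Ifi204 and Ifi205 fell, at -2.77 ± 0.28, -2.87 ± 0.40 and -2.97 ± 0.37, as did the chemokines Cxcl10 and Cxcl5 at -3.06 ± 0.53 and -2.47 ± 0.44. Of 22 listed interferon-stimulated genes 14 fell, 20 adjusted over the list alone, with medians of -2.44 in quiescent, -1.73 in vehicle and -1.24 in PRI-724 cells (adjusted p = 3.19e-41, adjusted p = 0.680 with an estimated correlation). Of 25 chemokine and inflammation genes 5 fell and 0 rose, 13 and 2 adjusted over the list alone (adjusted p = 5.52e-12, adjusted p = 0.541 with an estimated correlation). Of 11 MHC class I genes 1 fell, 7 adjusted over the list alone (adjusted p = 4.01e-11, adjusted p = 0.680 with an estimated correlation), and that was H2-K1 at -1.06 ± 0.18.

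Genes of plasma proteins made by hepatocytes were among those higher in the old samples. The plasma protein genes Hpx, Serpina1d, Serpina1c, Ambp, Pzp and Ahsg rose by 3.49 ± 0.31, 3.23 ± 0.35, 3.07 ± 0.31, 2.66 ± 0.28, 2.59 ± 0.39 and 2.56 ± 0.39. Saa2, an acute-phase protein, rose by 3.37 ± 0.54, the urinary protein genes Mup3 and Mup20 by 3.16 ± 0.34 and 2.71 ± 0.29, and Apob by 2.70 ± 0.24. Serpina1c, Serpina1d, Mup3 and Mup20 belong to families of near-identical copies, so the split between copies is uncertain. Of 17 listed hepatocyte genes 6 rose, 13 adjusted over the list alone, with medians of 3.04 in quiescent, 1.15 in vehicle and 0.64 in PRI-724 cells (adjusted p = 2.15e-16, adjusted p = 0.680 with an estimated correlation). The macrophage list had a median of 0.34 (0.62 in quiescent, -0.10 in vehicle and 0.37 in PRI-724 cells) and the endothelial list a median of -0.35 (-1.29 in quiescent, -0.36 in vehicle and 0.77 in PRI-724 cells), and neither was called (adjusted p = 0.103 and 0.0552).

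Lists of matrix, YAP/TAZ, cholesterol synthesis and contractile genes were called higher in old samples. Of 28 matrix genes 2 rose and 0 fell, 10 and 1 adjusted over the list alone, with medians of 0.25, 0.20 and 0.97 in quiescent, vehicle and PRI-724 cells (adjusted p = 4.29e-07, adjusted p = 0.680 with an estimated correlation). These were Tnc, tenascin C, at 1.34 ± 0.19 and Fn1, fibronectin, at 1.22 ± 0.21. Of 13 YAP/TAZ targets 0 rose, 10 adjusted over the list alone (median 0.75, adjusted p = 1.21e-08, adjusted p = 0.680 with an estimated correlation). Of 17 cholesterol synthesis genes 0 rose, 7 adjusted over the list alone (adjusted p = 2.41e-06, adjusted p = 0.680 with an estimated correlation). Of 17 contractile genes 1 rose, Tagln at 2.23 ± 0.37, 4 adjusted over the list alone (adjusted p = 0.00937, adjusted p = 0.692 with an estimated correlation, adjusted p = 0.552 without the young PRI-724 array and 0.559 without the old one). Col1a1 stood at 1.66 ± 0.39 (adjusted p = 0.126) and Acta2 at 1.46 ± 0.34 (0.121). In all 41 genes were higher and 39 lower (limma), with 1615 at an unadjusted p under 0.05, and after cyclic loess 2 were higher and 5 lower. At least 2-fold in all 3 pairs, 41 genes were higher and 33 lower, and 48 were 2-fold apart in opposite directions.

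Further lists of signalling, lipid and stress genes were called with age. Of 20 TGF-beta genes 0 rose, 4 adjusted over the list alone (adjusted p = 0.00671, adjusted p = 0.680 with an estimated correlation, 0.293 without the young and 0.292 without the old PRI-724 array). Of 17 growth factor genes 0 rose, 4 adjusted over the list alone (adjusted p = 0.00602, adjusted p = 0.680 with an estimated correlation). Of 23 retinoid and lipid genes 1 rose and 0 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.00275, adjusted p = 0.680 with an estimated correlation, 0.104 without the young and 0.103 without the old PRI-724 array). The gene that rose was Rbp4, the plasma carrier of retinol, at 1.72 ± 0.28. The hepatocyte list, called higher in the same samples, had a median of 1.72, and the cell source of Rbp4 was not tested. Of 15 p53 targets 0 rose, 2 adjusted over the list alone (adjusted p = 0.00937, adjusted p = 0.680 with an estimated correlation, 0.130 and 0.141 without the young and the old vehicle array, 0.0723 and 0.0719 without the young and the old PRI-724 array). Of 16 Nrf2 antioxidant genes 0 fell, 1 adjusted over the list alone (adjusted p = 0.000563, adjusted p = 0.680 with an estimated correlation, 0.606 and 0.573 without the young and the old vehicle array). Of 16 genes of hypoxia and glycolysis 0 fell, 0 also adjusted over the list alone (adjusted p = 0.0198, adjusted p = 0.692 with an estimated correlation, 0.973 without either vehicle array, 0.0504 with the mean of all probe sets of a gene).

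For age the p-values measure how alike the 3 states were, since the labels do not say whether the arrays of an age share a pool of mice, and they hold no spread between pools or animals. With state in the model, leaving out the young or the old array of a state leaves the same remaining pairs. The paired counts below, and the paired list values above, are thus the same check given for either array. With limma 0 genes passed without the young or the old PRI-724 array, with 1644 and 1642 at an unadjusted p under 0.05. Without the young or old quiescent array 220 and 215 passed, and without the young or old vehicle array 343 and 337.

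**Figure D3:**
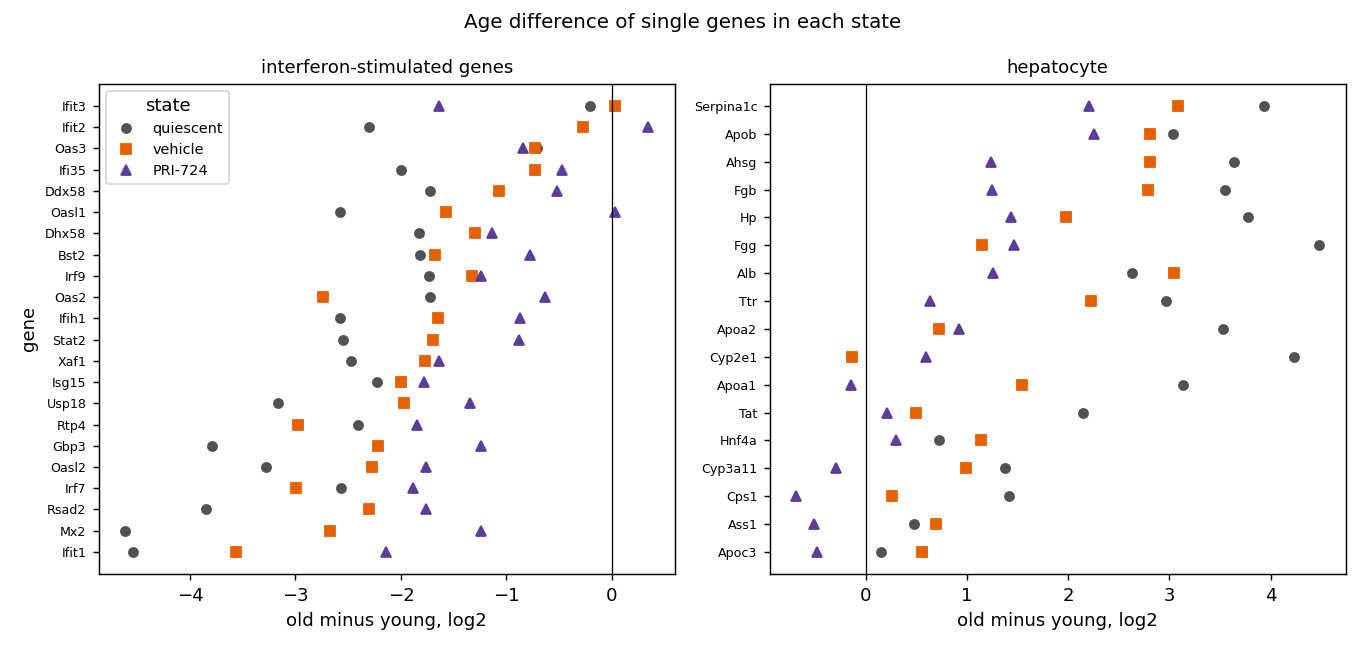
Old minus young log2 difference (x axis) of each tested gene (y axis) of the interferon-stimulated list on the left and the hepatocyte list on the right, with a symbol for each of the 3 states. The interferon list has medians of -2.44, -1.73 and -1.24 and the hepatocyte list medians of 3.04, 1.15 and 0.64 in quiescent, vehicle and PRI-724 cells.

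With 1 array for each age and state, the age difference of a response has no test. The young and old activation differences correlated across genes at 0.668 (Spearman 0.650), the PRI-724 minus vehicle differences at 0.571 (0.402) and the PRI-724 minus quiescent differences at 0.471 (0.282). The activation difference was at least 2-fold apart between ages in 1030 genes and the PRI-724 minus vehicle difference in 1940. After cyclic loess these were 1031 and 1266, and the young PRI-724 array, which enters the second count, had the narrowest signal range of the 6. The old pair had the smaller PRI-724 differences, with an SD across genes of 0.449 against 0.808 in the young pair.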

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

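The tests of a fault of the young PRI-724 array, of exchanged arrays, of a different response with age and of the age difference of matrix genes after cyclic loess, those on interferon-stimulated genes and the choice of leukocyte genes by quiescent signal were chosen only after the results were seen. The wider marker lists were written after the macrophage and endothelial lists had been seen to fall and before the values of their own genes were summarised, although Clec7a and Clec12a of the leukocyte list are also among the 10 genes with the largest fall.

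Some values pointed in opposite directions in young and old cells, and with 1 array for each group these differences were not tested. With activation the macrophage list had a median of 0.35 in the young and -0.59 in the old pair, a difference of -0.94, and the sinusoidal endothelial list -0.28 and 0.58, a difference of 0.86. Between PRI-724 and quiescent cells the neutrophil list had 0.38 and -0.28, a difference of -0.65, and Ccnd1 -1.63 and 1.75, a difference of 3.38. Probe sets without a single gene, which no comparison used, were also counted. Of 8946 such probe sets above the signal limit, 735 were at least 2-fold lower with activation in both ages (156 higher, 17 opposite), and 321 were higher with PRI-724 than with vehicle (69 lower, 25 opposite). No test was run on these counts, which cover probe sets not used in the report. The dimmest 25% of tested genes had medians of -0.18 in the young and -0.12 in the old pair with activation. With PRI-724 minus vehicle these were 0.37 and 0.00. A shift across dim signals is not separated from the counts.

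For the fall of macrophage and sinusoidal endothelial markers after PRI-724, a fault of the young PRI-724 array as the whole cause is argued against by the old pair, where the macrophage list had a median of -2.28 and the endothelial list -1.91. Of 11 further leukocyte and macrophage genes with a vehicle mean of 8 or more, a share of 0.909 fell by 1 or more in both ages, among them Lilrb4a (vehicle mean 11.6) at -2.94 and Clec7a (10.7), while Gpnmb (11.2) stood at -0.79. Over all 38 tested genes of that list 22 fell so (median -1.52) and Cx3cr1 stood at 1.69 in the young and 0.11 in the old pair, and of 11 genes chosen by a quiescent mean of 8 or more 8 fell. A median of -1.65 over 23 further endothelial genes, with Ehd3 (10.6) at -1.68 and Eng (12.0) at -0.77, points the same way, and fewer macrophages and endothelial cells in the treated cultures is a candidate explanation. Lower expression in cells that stayed is not separated from this, and a direct effect of the compound was not tested.

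For the larger fall of matrix genes in the young pair, the narrower signal range of the young PRI-724 array stays open as a cause. Among matched random lists the matrix median of -1.07 stood at percentile 0, and at percentile 0 also after cyclic loess. The random median was -0.35, with 95% of random medians between -0.62 and -0.09. These lists cannot decide the question, since they were matched on mean signal and not on vehicle signal. The matrix list had a median signal of 8.54 on the young vehicle array, against 6.57 on the young quiescent and 6.66 on the young PRI-724 array. Random genes were also drawn without regard to correlation, while the matrix list had an estimated correlation of 0.284, so the 95% ranges can be too narrow. The difference between ages itself (old minus young 0.68) stood beside a random median of 0.36 (95% between 0.16 and 0.58), so a large part of it is shared by genes of like signal, and after cyclic loess it was 0.34 beside a random median of 0.00 (95% between -0.19 and 0.20). An exchange with the young quiescent array is argued against by macrophage markers that were 3.51 lower (-3.51) than on the old quiescent array. A different response of young and old cells cannot be told apart from a difference between single arrays, since each group had 1 array. The labels also do not give the exposure time to C-82 for either age.

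For the lower interferon-stimulated genes in old samples, fewer macrophages as the whole cause are argued against by a macrophage median of 0.34 (SD over genes 0.448). By state it was 0.62 in quiescent, -0.10 in vehicle and 0.37 in PRI-724 cells, with 2 of 14 genes of the same sign in all pairs. Dilution by hepatocyte RNA as the whole cause is argued against by a matrix median of 0.50 (0.25, 0.20 and 0.97), where a fall of the size of the interferon list was needed. The matrix list was itself called higher with age, and in quiescent cells the MHC class I and chemokine lists fell (medians of -1.28 and -0.78). A part from dilution therefore stays open. Fewer sinusoidal endothelial cells as the whole cause are argued against in PRI-724 and vehicle cells, where the endothelial medians of 0.77 and -0.36 lay above the interferon medians of -1.24 and -1.73 by 2.01 and 1.37, more than their joint spread over genes (0.955 and 1.03). In quiescent cells this stays open, since the endothelial median of -1.29 lay above the interferon median of -2.44 by 1.16, within their joint spread (SDs over genes 1.04 and 1.09). The joint spread is over genes within lists and is no measure of error between arrays. The line drawn between the states is therefore descriptive and holds for these arrays only. A difference between the pools other than age cannot be told apart from age (interferon median -1.70), since each age and state had 1 array and the labels do not say which arrays share a pool, and age itself stays open and untested.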

How the results depend on the processing

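Genes past the threshold kept their direction under each alternative in which they were tested, while the counts moved, and the cause was not tested except where stated. In part this was fixed in advance. For a comparison of states, dropping the trend, the age term or arrays of the state not compared leaves the estimate of each gene unchanged. For age, dropping the trend or the state term does so. The count of 0 named genes that changed direction is fixed under those settings too. Leaving out the young or the old array of a state is the same check for age, since the remaining pairs are the same. It is also the same check for a comparison that does not use that state. Without age (or state) in the model, higher and lower counts were 97 and 17 for activation, 5 and 86 for PRI-724 minus vehicle, 46 and 171 for PRI-724 minus quiescent, and 0 and 0 for age (limma, 581 at an unadjusted p under 0.05). With only the 2 states compared they were 362 and 119, 185 and 780, and 407 and 657. After cyclic loess 338 genes were higher with activation, 3 higher and 100 lower with PRI-724 minus vehicle, and 2 higher and 5 lower with age, so 28.6% were higher against 51.3% before. After quantile normalization, chosen after seeing the data, the counts were 246 and 85, 2 and 82, and for age 4 and 8. With the lowest 50% of genes left out, 25 were higher with PRI-724 minus vehicle. Leaving out each array in turn, which leaves 1 residual degree of freedom and assumes that the lone sample varies like the others, gave 193 to 973 higher and 115 to 257 lower genes for activation, 0 to 191 and 0 to 777 for PRI-724 minus vehicle, 0 to 406 and 0 to 647 for PRI-724 minus quiescent, and 0 to 227 and 0 to 116 for age. The counts of 0 came without the young PRI-724 array (unadjusted p under 0.05 in 997, 2763 and 1644 genes) and, for age, also without the old one (1642). The numbers of called lists (15, 17, 14 and 14) became 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 0 with fry, chosen after seeing the data, and ranged over 14 to 18, 12 to 17, 9 to 14 and 12 to 16 when arrays were left out. By its construction a 1.5-fold limit in every pair gave more genes, 1772 and 643, 269 and 936, 827 and 679, and 168 and 86, and 51 genes were 2-fold lower with age after cyclic loess. The PRI-724 response was 2-fold apart between ages in 1266 genes after cyclic loess. Of the named genes past the threshold, 82, 43, 60 and 29 in the 4 comparisons, 0 changed direction, and 339 of 1146, 161 of 600, 204 of 840 and 152 of 376 values lost their call. In the model the arrays of an age were paired through the age term, and the young and old arrays of a state through the state term. By replicate number no paired analysis was possible because every array is replicate 1. Genes under the signal limit, such as Lef1 and Birc5, were not tested.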

Other observations

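The tests of this part were planned, apart from the view of the splits with 1 array of each state, which was chosen after the result was seen.

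The Wnt pathway list was not called with activation, where 3 of 31 genes rose (adjusted p = 0.816), or between PRI-724 and quiescent cells, where 2 fell (adjusted p = 0.357). The receptor genes Fzd6 and Fzd1 rose by 1.30 ± 0.25 and 1.06 ± 0.27, and Wnt5a, a ligand that signals largely without beta-catenin, by 1.19 ± 0.28. Between PRI-724 and quiescent cells Wnt2 and the receptor gene Fzd4, both expressed by liver endothelium, fell by 2.32 ± 0.44 and 2.13 ± 0.47. Crebbp stood at -0.85 ± 0.24 with activation (adjusted p = 0.0742) and Ctnnb1 at -0.62 ± 0.23 (0.146).

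Single genes of lists that were not called passed the threshold. The list of aryl hydrocarbon receptor targets had adjusted p of 0.816, 0.209, 0.582 and 0.376 in the 4 comparisons, and the smooth muscle or pericyte list 0.898, 0.635, 0.785 and 0.893. Cyp1b1 rose by 2.17 ± 0.38 with activation and Gstm2, a glutathione transferase, by 2.08 ± 0.32, and Cyp1a2, a hepatocyte cytochrome P450, was higher by 2.14 ± 0.33 in old samples. Rgs5, a pericyte regulator of G protein signalling, fell by 1.66 ± 0.29 with activation and Mcam, an adhesion molecule, rose by 1.58 ± 0.36, and Mcam fell by 1.73 ± 0.36 after PRI-724. Itgax, an integrin of dendritic cells and macrophages, fell by 2.49 ± 0.43 after PRI-724. The lists of T cells, B cells, neutrophils, dendritic cells, cholangiocytes, portal fibroblasts, smooth muscle or pericytes, platelets and adipocytes were not called in any of the 4 comparisons, with lowest adjusted p of 0.0774 (cholangiocytes, activation), 0.0915 (cholangiocytes, PRI-724 minus vehicle), 0.187 (B cells, PRI-724 minus quiescent) and 0.0810 (T cells and platelets, age). NK cell and erythroid lists had 2 and 1 tested genes and were not tested as lists.

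Of the 10 splits of the 6 arrays into 3 and 3 with state in the model, 3 gave as many genes as the split by age, the real split included. The real split gave 80 genes and the highest of the others 119. With 10 splits a share under 0.05 cannot be reached. Of the 4 splits with 1 array of each state on either side, the real split gave 80 genes and the other 3 gave 0, 0 and 0 (limma, with 684, 477 and 255 genes at an unadjusted p under 0.05, against 1615 in the real split), and 4 splits cannot reach that share either. The other 3 reverse the age difference of 1 state, so an age difference shared by the states enters their residual. Their lower counts are thus no reference for chance. The 2 splits with 119 genes parted the quiescent arrays and kept the vehicle pair and the PRI-724 pair together. With state in the model they are the same fit, and it tests the age difference of the quiescent pair. The other splits without 1 array of each state on either side rest in the same way on the vehicle pair (4 genes) or the PRI-724 pair (0 genes). These splits are thus age differences themselves, and the count of 3 is no measure of chance.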
